A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

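RNA levels were measured on 2-colour DNA microarrays in *Saccharomyces cerevisiae* cells of the laboratory strain BY4741 carrying a wsc1 mutation. WSC1 encodes a plasma membrane sensor that reports cell wall stress to the cell wall integrity pathway. Caspofungin is an echinocandin drug that inhibits the synthase of β-1,3-glucan, the main structural polymer of the yeast wall. Per the labels, a culture growing at 24 °C was divided, 1 part received 15 ng/ml caspofungin, and both parts were collected 2 h later. In replicate 1 the untreated RNA carried the dye Cy5 and the caspofungin RNA the dye Cy3, and in replicate 2 the dyes were exchanged. The labels speak of 2 cultures and of 4 arrays with exchanged dyes, and they do not say whether the 2 deposited columns come from 2 cultures or from both dye orientations of 1 culture. The p-values of single genes therefore measure only the spread between these 2 columns, which may be technical.

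The deposited table holds 1 log2 ratio per ORF and replicate, and its scale was checked on the values. When 2 was raised to the power of each value, 100% of the results in each column had no more than 4 decimals, within a tolerance of 0.001 of the last decimal. No other base and no inverse gave this for more than 0.378% of the values, so the values were taken as log2 of a dye ratio. Background correction, normalization, averaging of spots and the rule that left ORFs blank are not given in the sources used here. The direction of the ratio, Cy5 over Cy3 or the reverse, is not given either, and neither is any centring. The column medians were -0.07 in replicate 1 and -0.04 in replicate 2. The table held 6207 ORFs and 2 control entries, and the controls were kept out of all tests. No spot intensities were used, so signal over background is unknown, and the number of arrays limits the precision. Gene symbols came from the RefSeq gene table of the organism, in which 5654 of the 6207 ORFs were matched; the other 553 kept the name the table gives them. WSC1 is listed there under the synonym SLG1.

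The following choices were made before the data were examined: the test, the rule for turning a column, the gene lists, the rule for named genes and the alternatives except those said to be added. Because the 2 deposited columns were correlated below 0, both were taken as the same dye ratio, which the labels do not state. The sign of replicate 1 was therefore turned, so that the caspofungin RNA stood in the same place of the ratio in both. The positive side is thus the side on which the deposited value was above 0 where the caspofungin RNA carried Cy5. It means more RNA with caspofungin if the ratio is Cy5 over Cy3, and less RNA if the ratio is the reverse. Values are given as mean ± SD of the 2 turned log2 ratios (n = 2). An average of both dye orientations cancels a dye effect that is equal in both. Such an effect stays in the SD and in the spread that the gene test uses.

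Each of the 3117 ORFs with a value in both columns was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The number of ORFs with a mean beyond 2-fold and the same sign in both columns was given beside it. Of the 24 gene lists, the 21 with at least 5 measured genes were tested with camera from limma at a preset correlation of 0.01 (two-sided, adjusted over the lists). This test compares the members of a list with the other genes. Its p-values take genes and not columns as units, so they do not measure how well a list repeats between the replicates. The lists covered cell wall stress targets, cell wall integrity signalling, β-glucan, chitin, environmental stress, heat shock chaperones, Crz1 targets, ribosome biogenesis, cytosolic ribosomal proteins, mating, cell cycle regulators, histones and phosphate. They also covered Gcn4 targets, sulfur, iron, respiration, glycolysis, hexose transporters, ergosterol, drug resistance, TIR and DAN mannoproteins and the genes deleted in the strain. Of the tested lists, 1 is not reported here, and it was kept in the adjustment over the lists. The median of each list was placed among 10000 random lists of the same size. These could not be matched on expression, because no levels were used.

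Named genes were up to 10 per side with the largest mean among those past the threshold, filled up by size among genes with the same sign in both columns. Up to 4 members of each list past its test, 4 of the cell wall stress list, 4 of the glucan list and the genes deleted in the strain were added. Genes named outside this rule are said to be chosen after their values were seen.

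The test was checked on simulated data of 3117 genes and 2 columns, with spreads drawn from the limma prior of the data and 200 changed genes, in 20 draws. It called 77% of the genes changed 2-fold and 97% of those changed 4-fold, with a mean of 10.85 unchanged genes called per draw. A list of 15 genes shifted by 0.25 was called in 20 of 20 draws, and 2 unshifted lists were called in all draws together. The simulated genes were independent of one another, and the simulated columns had no shift. In the data, 30 ORFs had a mean beyond 2-fold, and the adjustment is stricter when fewer genes change. These shares may therefore overstate the power in the data, and 0 calls there do not show that no gene changed. Alternatives were centring or scaling of the columns, the opposite turning, a robust prior, a minimum fold of 1.2, a plain one-sample statistic, other size thresholds, ORFs measured in 1 column, other list tests, and leaving out each replicate. In 2 alternatives added after seeing the data, the prior of the spread was exchanged between the centred and the uncentred fit. Additional counts were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.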

Results

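The data set held 2 microarray comparisons of caspofungin-treated with untreated wsc1 mutant cells, with the dyes exchanged between them. Replicate 1 gave a log2 ratio for 3705 of 6207 ORFs and left 40.3% blank, and replicate 2 gave one for 3166 and left 49.0% blank. Both replicates had a value for 3117 ORFs, and 2453 were blank in both. The deposited ratios had an SD of 0.385 in replicate 1 and 0.315 in replicate 2. The mutated gene WSC1 was blank in both replicates. Both RNAs of each comparison came from the mutant, so a ratio could not have shown its absence in any case. Of the marker genes deleted in BY4741, MET17 and URA3 were blank in both replicates as well. HIS3 and LEU2 had values, with means of 0.24 ± 0.24 and 0.29 ± 0.25 (SD, n = 2). After turning, HIS3 had 0.071 and 0.41 in replicates 1 and 2, and LEU2 had 0.12 and 0.47. Whether their probes lie outside the deleted parts is not given in the sources used here, so these values do not check the strain.

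The comparison asked which genes of the wsc1 mutant differed in RNA level after 2 h in 15 ng/ml caspofungin. The genes with the greatest ratios lay on the negative side, which is the side of lower RNA with caspofungin only if the ratio is Cy5 over Cy3. RPS12, a protein of the small ribosomal subunit, had a mean log2 ratio of -1.71 ± 0.26 (SD, n = 2), a size of 3.28-fold. INO80, the ATPase of a chromatin remodelling complex, had -1.46 ± 0.03 (2.75-fold), and SSA3, a heat-inducible Hsp70 chaperone, had -1.30 ± 0.48 (2.47-fold). On the opposite side, SHR5, a subunit of a palmitoyltransferase that acts on Ras, had 0.98 ± 0.32 (1.97-fold). No single gene passed the test, with an adjusted p of 0.366 for each of these 4 (limma).

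The other negative ratios of greatest size belonged to genes of varied function. RPS22B, also of the small ribosomal subunit, had -1.59 ± 1.12. YDR341C, the cytosolic arginyl-tRNA synthetase, had -1.43 ± 0.90, and CKA1, a catalytic subunit of casein kinase 2, had -1.38 ± 0.66. PDR16, a phosphatidylinositol transfer protein of the drug resistance network, had -1.33 ± 0.94. KTR7, a putative mannosyltransferase, had -1.32 ± 0.94. The ORF YHR145C had -1.30 ± 0.74, and the retrotransposon ORF YHR214C-B had -1.29 ± 1.00. These 7 differed between the replicates by enough that leaving out 1 replicate moved the mean by over 1.5 times. After turning, the values in replicates 1 and 2 were -2.38 and -0.80 for RPS22B, -2.07 and -0.80 for YDR341C, and -1.84 and -0.91 for CKA1. They were -1.99 and -0.66 for PDR16 and -1.98 and -0.66 for KTR7. Replicate 2 had the greater size for YHR145C (-0.78 and -1.83) and YHR214C-B (-0.58 and -2.0). For RPS22B, INO80, PDR16 and KTR7, another gene with a deposited value above 1 in replicate 1 stood within 3 places in the order of ORF names. These 10 genes had the same sign in both replicates because the naming rule admitted no others.

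On the positive side the ratios were smaller. AIM19, which encodes a mitochondrial protein, had 0.82 ± 0.15, and SRB2, a Mediator subunit, had 0.79 ± 0.33. DPM1 and OST3 both act in glycosylation, DPM1 as dolichol phosphate mannose synthase and OST3 in the oligosaccharyltransferase. Their means were 0.75 ± 0.17 and 0.71 ± 0.13. MF(ALPHA)2, an α-factor pheromone gene, had 0.70 ± 0.24, and ADO1, adenosine kinase, had 0.69 ± 0.30. YCRX07W had 0.75 ± 0.29, YBL083C 0.72 ± 0.37 (0.46 in replicate 1 and 0.98 in replicate 2) and YDR476C 0.69 ± 0.26. None passed the test, with an adjusted p of 0.366 for each.

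**Figure D1:**
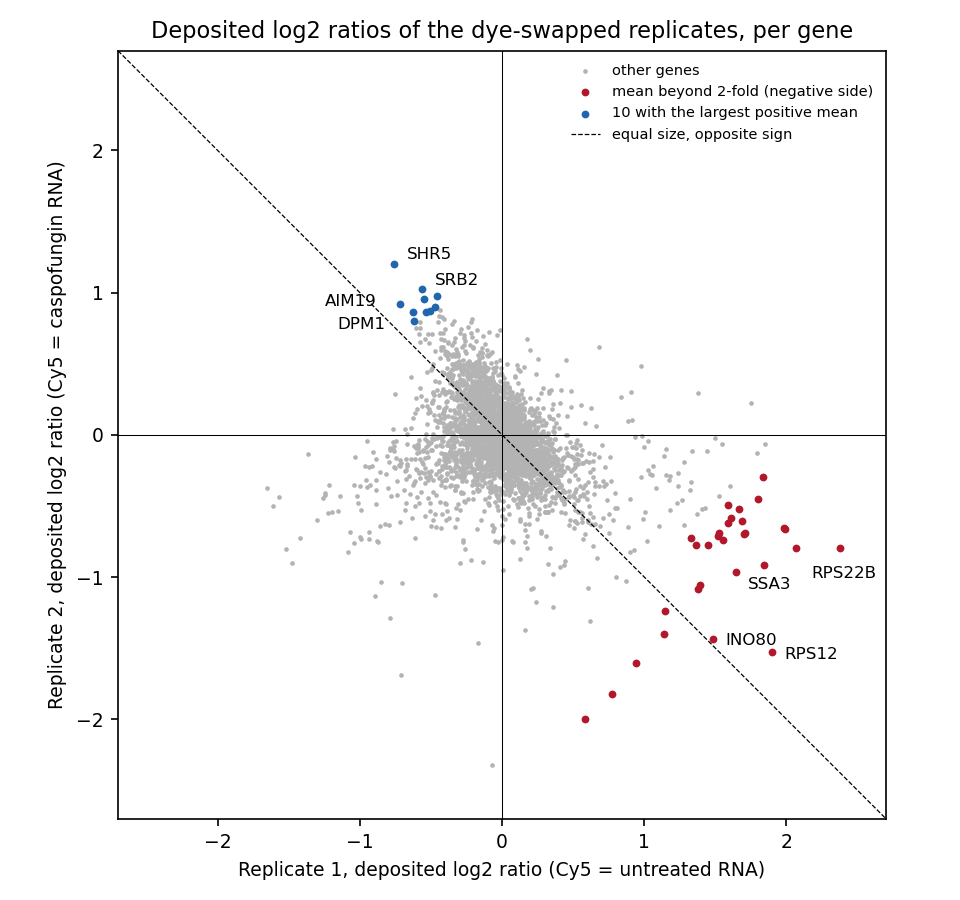
Deposited log2 ratio of replicate 1 (horizontal, Cy5 on untreated RNA) against replicate 2 (vertical, Cy5 on caspofungin RNA) for the 3117 ORFs measured in both, 1 point per ORF. The 30 ORFs with a mean beyond 2-fold (red) lie at the lower right, and the 10 with the greatest positive means (blue) at the upper left.

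Of the 3117 ORFs, 0 passed an adjusted p of 0.05 in limma, and the lowest adjusted p was 0.366. At an unadjusted p of 0.05, limma gave 417 ORFs, 175 positive and 242 negative, where 156 would be expected by chance. Under the opposite turning it gave 94, 7 positive and 87 negative. The turning followed the sign of the correlation in these same values, which favours a count above chance. With the plain one-sample statistic the counts were 0 adjusted and 264 unadjusted, with the robust prior 0 and 415, and with a minimum fold of 1.2 they were 0 and 122. By size, 30 ORFs had a mean beyond 2-fold with the same sign in both replicates, and all 30 were negative. At 1.5-fold there were 126, of which 23 were positive and 103 negative. With each column centred on its median, limma called 115 ORFs, 24 positive and 91 negative, including all 20 genes named by size; its estimated prior then had 17.1 degrees of freedom, against 2.64 as deposited. The count beyond 2-fold was 10 when replicate 1 was not turned, 87 in replicate 1 alone and 27 in replicate 2 alone.

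Genes of the cell wall stress response, targets of the kinase Slt2 and the transcription factor Rlm1 with associated wall genes, lay on both sides. Of 25 members on the array, 17 had a value in both replicates. GSC2, KDX1, YPS3, PRM10 and PTP2 were blank in both. SLT2, PRM5 and GFA1 were blank in replicate 2, with -0.098, -0.32 and -0.32 as deposited in replicate 1. These blank members were picked after the values were seen, and the test does not cover them. Of the 17 measured members, 9 were positive and 8 negative, with a median of 0.04 (camera adjusted p = 0.640). Over all genes or adjusted over the list alone, 0 members passed. The list median after turning was -0.10 in replicate 1 and 0.19 in replicate 2. PST1, a GPI-anchored wall protein, had the greatest mean, 0.57 ± 0.21 (adjusted p = 0.366), and DFG5, a putative wall glycosidase, had -0.34 ± 0.09 (adjusted p = 0.366). FKS1, the catalytic subunit of β-1,3-glucan synthase and the target of the drug, had 0.34 ± 0.59 (adjusted p = 0.544). Its turned values were 0.76 in replicate 1 and -0.08 in replicate 2. BGL2, a wall glucanosyltransferase, had 0.33 ± 0.34 (adjusted p = 0.426), with 0.087 in replicate 1 and 0.57 in replicate 2.

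The genes of β-glucan synthesis and remodelling leaned to the positive side, with 13 of 14 measured members positive and a median of 0.17, at percentile 99.1 of random lists. Of the 14, 9 had the same sign in both replicates (64.3%, against 64.1% of all ORFs). The list did not pass its test (camera adjusted p = 0.064). SUN4, of a family of glucanase-related wall proteins, had 0.30 ± 0.07 (adjusted p = 0.372) and GAS5, a β-1,3-glucanosyltransferase, had 0.21 ± 0.13 (adjusted p = 0.440), with 0.12 in replicate 1 and 0.31 in replicate 2. FKS1 and BGL2, given above, belong to this list too. None of the 14 members passed over all genes or adjusted over the list alone. Chitin genes had a median of 0.02, with 4 of 7 positive (camera adjusted p = 0.960), and their mean was -0.002. Components of cell wall integrity signalling had a median of 0.05, with 4 of 8 positive (camera adjusted p = 0.960). Their median after turning was 0.12 in replicate 1 and -0.13 in replicate 2.

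Heat shock chaperones lay mostly on the negative side, with 14 of 17 members negative and a median of -0.29, at percentile 0.01 of random lists. Their median after turning was -0.13 in replicate 1 and -0.39 in replicate 2, 10 of the 17 had the same sign in both (58.8%), and the list missed the threshold (camera adjusted p = 0.051). SSA3 and SSA4, both inducible Hsp70 genes, had -1.30 ± 0.48 and -0.66 ± 0.14, and these 2 members passed when adjusted over the list alone, against 0 over all genes. Ribosome biogenesis genes had 13 of 16 members negative and a median of -0.16 (camera adjusted p = 0.059). Their median after turning was -0.012 in replicate 1 and -0.29 in replicate 2, and 8 of the 16 had the same sign in both (50%). Among them NOP1, a methyltransferase of the small nucleolar ribonucleoproteins, passed adjusted over the list alone, with -1.19 ± 0.07 and a neighbour above 1 in replicate 1 within 3 places. SSA4 and NOP1 were chosen after their values were seen. Cytosolic ribosomal proteins had 77 of 125 negative and a median of -0.06 (camera adjusted p = 0.059), 93 had the same sign in both replicates (74.4%), and 0 passed adjusted over the list alone. With an estimated correlation the lowest adjusted camera p of any list was 0.893, and with fry it was 0.341. With 2 columns both of these tests have 1 degree of freedom, so they could hardly call any list. The unadjusted camera p of the β-glucan list went from 0.012 to 0.23, though its estimated correlation of -0.077 lay below the preset 0.01. The values of 0.893 and 0.341 are therefore not evidence against the lists. In the test on ranks, 4 lists passed, heat shock, ribosome biogenesis, ribosomal proteins and β-glucan (adjusted p = 0.048 each), and with centred columns the first 3 of these passed (adjusted p = 0.012, 0.032 and 0.037).

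**Figure D2:**
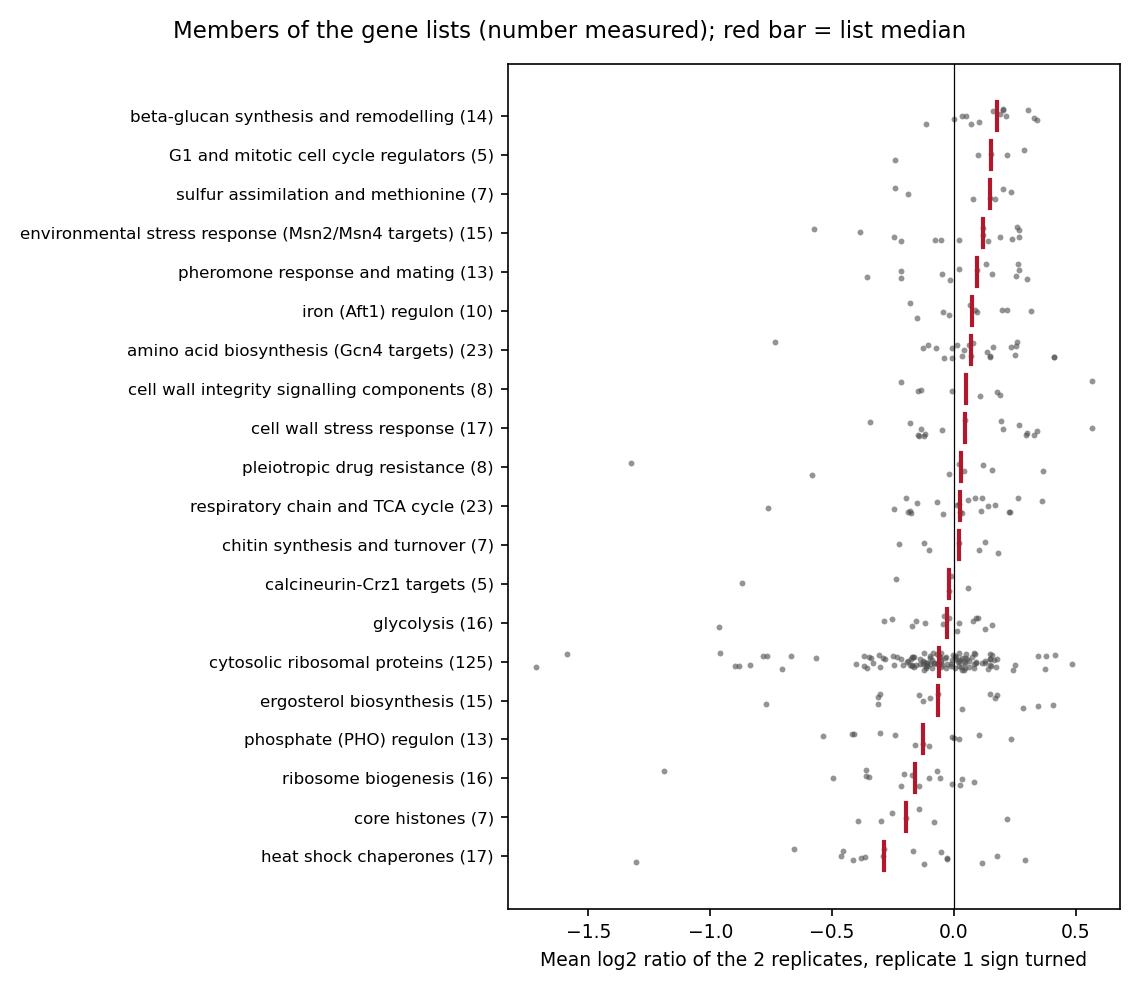
Mean of the 2 turned log2 ratios (horizontal) for each measured member of 20 of the 21 tested gene lists, 1 point per gene, with the number of measured members in parentheses and the list median as a red bar. Of the lists shown, heat shock chaperones have the lowest median, -0.29, and β-glucan genes the highest, 0.17; neither list passed its test.

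Of the other lists, core histones had 6 of 7 members negative, with a median of -0.20 (camera adjusted p = 0.134). The phosphate regulon had 9 of 13 negative, with a median of -0.13 (camera adjusted p = 0.138). Targets of Gcn4, the activator of amino acid biosynthesis, had 16 of 23 positive, with a median of 0.07 (camera adjusted p = 0.138). The Crz1 targets had 4 of 5 negative, with a median of -0.02 (camera adjusted p = 0.411). Their median after turning was 0.094 in replicate 1 and -0.18 in replicate 2, and 2 of the 5 had the same sign in both. Of the 5 only CRZ1 itself, the calcineurin-regulated transcription factor, passed adjusted over the list alone, with -0.87 ± 0.33. CRZ1 was chosen after its values were seen. G1 and mitotic regulators had a median of 0.15 (adjusted p = 0.506), sulfur assimilation 0.15 (0.748) and the environmental stress response 0.12 (0.960). The turned medians in replicates 1 and 2 differed in sign for sulfur (0.043 and -0.0082) and environmental stress (0.081 and -0.089). Mating genes had a median of 0.10 (0.640), with 0.078 in replicate 1 and 0.0078 in replicate 2 after turning, and the iron regulon had 0.08 (0.640), with 0.046 and 0.095. Glycolysis had a median of -0.03 (0.639) and ergosterol biosynthesis -0.07 (0.960). Respiratory genes had a median of 0.02 but a mean of -0.01 (0.871), and drug resistance genes had a median of 0.03 but a mean of -0.15 and a negative camera direction (0.960). Hexose transporters, with 4 measured genes and a median of 0.01, TIR and DAN mannoproteins, with 3 and 0.32, and the deleted genes, with 2 and 0.27, were not tested. Their turned medians in replicates 1 and 2 were 0.065 and -0.045, 0.19 and 0.33, and 0.094 and 0.44, in that order.

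The agreement of the replicates was limited. Across the 3117 ORFs, which are not independent replicates, the deposited columns had a Pearson r of -0.29 and a Spearman rho of -0.33. After the turning, which followed the sign of this correlation, 1997 ORFs (64.1%) had the same sign in both. The SD across ORFs was 0.275 for the mean of the turned ratios and 0.204 for the mean of the deposited ratios, and both hold the noise of each replicate. Dye effects of single genes would also lower the agreement after turning, and they were not separated from noise. On the negative side, 63 ORFs were beyond 2-fold in replicate 1 and 25 in replicate 2, with 6 in both, where 0.505 would be shared by independent lists. On the positive side the counts were 24 and 2, with 0 in both.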

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

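The exchange of priors was chosen after the result was seen; the other alternatives were planned. The count of called ORFs, 0 as deposited, remained 0 with the opposite turning, the robust prior, the minimum fold of 1.2, the plain statistic and ORFs measured in at least 1 column. It was 115 with each column centred on its median and 103 when columns were also scaled to one median absolute deviation. The limma prior had 2.64 degrees of freedom as deposited and 17.1 after centring. Centred columns with the prior of the uncentred fit gave 0 calls, and columns as deposited with the prior of the centred fit gave 121. The count thus moved with the estimated prior. That prior itself changed when the columns were centred, so the shift of the columns is not excluded as the source. ORFs beyond 2-fold numbered 126 at 1.5-fold, 10 under the opposite turning and 27 to 87 when a replicate was left out. Of the gene lists, 4 passed on ranks, 3 with centred and 3 with scaled columns, and the cause was not tested. With an estimated correlation 0 of 21 passed (lowest adjusted p 0.893), with fry 0 (0.341) and under the opposite turning 0 (0.131). The last value belonged to the cell wall stress list, on the positive side, and to ribosome biogenesis, on the negative side. The test with an estimated correlation and fry each have 1 degree of freedom here, so their counts say little. Leaving out the ORFs beyond 2-fold in either replicate gave a Pearson r of 0.29 between the turned columns, the same as with all ORFs. Under the opposite turning, in which replicate 1 kept its deposited sign, list medians changed sign to -0.043 for cell wall integrity signalling, -0.00033 for β-glucan, -0.010 for environmental stress, -0.028 for mating, -0.034 for G1 and mitotic regulators and -0.057 for sulfur. Those of drug resistance (-0.034), phosphate (0.028), glycolysis (0.043), ergosterol (0.021) and ribosomal proteins (0.010) did so too. So did the means of RPS12 (0.19), RPS22B (0.79), INO80 (0.023), YDR341C (0.64), CKA1 (0.46), PDR16 (0.66), KTR7 (0.66), SSA3 (0.34), DFG5 (0.060) and FKS1 (-0.42). When each replicate was left out, medians spanned 0 for cell wall stress (-0.10 to 0.19), cell wall integrity signalling (-0.13 to 0.12), chitin (-0.019 to 0.059), environmental stress (-0.089 to 0.081) and Crz1 targets (-0.18 to 0.094). They also did for sulfur (-0.0082 to 0.043), ergosterol (-0.017 to 0.0091) and drug resistance (-0.0072 to 0.065), as did FKS1 (-0.079 to 0.76); the cause was not tested. Medians of tested lists that kept their sign but moved by over 1.5 times were those of heat shock (-0.39 to -0.13), ribosome biogenesis (-0.29 to -0.012), mating (0.0078 to 0.078), iron (0.046 to 0.095), Gcn4 targets (0.10 to 0.11, against 0.07 with both), respiration (0.029 to 0.043, against 0.024) and glycolysis (-0.058 to -0.031, against -0.030). With 1 replicate left there was no test. Averaging of spots could not be varied, because the table holds 1 value per ORF. The test of the ratios against 0 was itself paired, because each ratio already holds both RNAs of its replicate.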

Other observations

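The tests in this part were chosen after the values were seen, with the following exceptions. Those of unnamed ORFs and of windows of ORFs were chosen before, as was the camera test of the cell wall stress list. Reading the direction of the ratio from that camera test was chosen afterwards. The genes named here were chosen after their values were seen. Families of genes sharing a name stem and holding at least 8 measured members were tested with camera. Of 40 families, 0 passed (lowest adjusted p 0.130), and 8 were at an unadjusted p of 0.05. With an estimated correlation the lowest adjusted p was 0.909, but that test has 1 degree of freedom here and says little. The 8 families at an unadjusted p of 0.05 are described here. The FMP genes, named for proteins found in mitochondria, had 8 of 9 members positive and a median of 0.18, but the turned median was 0.30 in replicate 1 and 0.015 in replicate 2. The RPS genes of the small ribosomal subunit had 33 of 53 negative, with a median of -0.06. Proteasome subunits lay mostly on the negative side, with 7 of 10 PRE genes (median -0.15) and 10 of 12 RPN genes (median -0.10, with -0.076 in replicate 1 and -0.19 in replicate 2). Translation initiation factors of the TIF family had 7 of 8 members negative, with a median of -0.22, and turned medians of -0.12 in replicate 1 and -0.27 in replicate 2. Among the GPI genes, most of which act in the synthesis of the membrane anchor of wall proteins, 7 of 8 were positive, with a median of 0.16. The AIM genes had 14 of 19 positive, with a median of 0.10. PAU genes of the seripauperin family had 9 of 12 members negative, with a median of -0.16.

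Ergosterol genes lay on both sides. Of 15 measured members, 14 had the same sign in both replicates, against 64.1% of all ORFs. This was not particular to them, as 12 of 13 mating genes and 7 of 7 core histones did so too. ERG28, ERG2 and ERG3 had means of 0.40 ± 0.03, 0.35 ± 0.23 and 0.28 ± 0.14, and ERG10, ERG27 and ERG20 had -0.77 ± 0.33, -0.31 ± 0.02 and -0.31 ± 0.09 (SD, n = 2). The deposited values in replicates 1 and 2 were -0.18 and 0.51 for ERG2 and -0.18 and 0.38 for ERG3, so their means rested more on replicate 2. The fry test for changes in either direction gave an adjusted p of 0.014 for this list and 0.017 for the cell wall stress list. Of 1000 random lists of the same size, 0.6% and 1.3% gave as low a mixed p. These were the lowest shares among the 21 lists and were not adjusted for that choice. The number of ergosterol members with the same sign did not pass a hypergeometric test adjusted over the lists (adjusted p = 0.123), so chance was not excluded.

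The ORFs beyond 2-fold were all on the negative side. A defect or noise of replicate 1 alone is argued against as the whole cause, because the 63 ORFs above 1 in replicate 1 and measured in both had a deposited median of -0.515 in replicate 2, below the range of -0.127 to 0.041 that held 95% of random lists. Of these 63, 2 were above 0 in replicate 2. This argues against ratios that follow the dye only if both columns hold the same dye ratio. That was inferred from the correlation of these same columns and is not given by the labels, so a dye effect is not excluded. The extremes were clustered, though, with 13 pairs of the 69 ORFs above 1 in replicate 1 within 3 places in ORF order, against 0 to 6 in 95% of random draws, so a neighbourhood effect of spots or of genes may contribute. Such a neighbour was found for 7 of the 30 ORFs beyond 2-fold and 25 of the 69 ORFs above 1 in replicate 1, against 5.31% of the other ORFs measured in replicate 1. A response to caspofungin stays open and untested, because no array of untreated against untreated cells was analysed here.

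The share of ORFs blank in at least 1 replicate, 49.8% in all, ran from 22.9% on chromosome II to 65.8% on chromosome XV. Loss of a part of the array whatever the RNA is argued against, since 2 of 85 ribosomal protein and glycolysis genes on the 8 chromosomes with the highest shares were blank (2.35%, exact 95% interval 0.286 to 8.24). An excess of unnamed ORFs is argued against as well, because the gap was 47.1 percentage points among named genes and 42.8 among all ORFs. Position in ORF order within chromosomes remains a candidate explanation, as the variance of the blank share between windows of 96 ORFs was 300.1, against 195 to 213 in 95% of shuffles. No biological explanation was tested.

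The cell wall stress genes measured in both replicates, 17 of the 25 on the array, did not settle the direction of the ratio, with a camera p of 0.427. Under the opposite turning this list lay on the positive side with a camera p of 0.0082 (adjusted p = 0.131). Its result thus depended on the turning, and it did not pass in either. These cells also carry a mutation in a sensor of that pathway, so a rise of these genes with the drug is not given in this strain. Cy5 over Cy3 and the reverse cannot be told apart here. The control entry named Arabidopsis had 0.29 in replicate 1 and 0.28 in replicate 2, and the entry named 3XSSC had -0.12 and -0.17. Neither changed sign with the dyes. Of the 588 ORFs measured in replicate 1 only, 21 were beyond 2-fold, among them ERR3 at 2.60 and SAC3 at -2.57 as deposited. Of the 49 measured in replicate 2 only, 0 were, too few ORFs to show a difference from replicate 1.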
